A study of Mus musculus with 6 samples.

How the data were processed

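RNA was extracted with Trizol from the tumours of 6 mice, and 200 ng of total RNA per tumour was turned into biotin-labelled sense-strand DNA, per the labels' protocols. Hybridisation was to the Affymetrix Human Gene 1.0 ST platform, per the series' design text. The labels give the organism as mouse, the host; the tumour cells and the array are human. Group and replicate number came from the sample titles. How the control mice were treated is not given in the sources used here, and the treatment text stands word for word on the control samples too.

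The authors deposited 1 table of log2 values with 1 column per array. The scale was read from the values, which run from 1.08 to 13.2 with near-equal quartiles in every array. Partek 6.6 is named in the submitters' processing notes; the background correction, the normalization and the summarization of probes are not given in the sources used here. Scanner files were not used here, so no detection call or hybridization control was available, and dim values are described by their rank only. No genome was given, and no chromosomal positions are printed.

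Gene names came from the platform annotation, which gave 1 symbol to 19460 probe sets and several to 1754. The other 12083 probe sets are unnamed here; they and those with several symbols entered none of the comparisons by gene or list and were tested apart. Of several probe sets of a gene (769 genes) the one with the highest mean over all arrays was kept, which left 18417 genes. Values were not normalized again and dim genes were not removed.

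The BL-8040 and control groups, 3 arrays each, were compared per gene with lmFit and eBayes of limma 3.58.1 in R 4.3.3, two-sided, without a replicate block, and p-values were adjusted after Benjamini and Hochberg over all 18417 genes. A gene was called at an adjusted p under 0.05. Differences are BL-8040 minus control on the log2 scale and folds are their antilog; SE is the moderated standard error. The design text names 3 mice per group, so the spread is taken to include that between animals. An exact permutation test of 3 against 3 arrays cannot give a p below 0.1.

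Before the data were examined, 29 gene lists were fixed from general knowledge. They cover the CXCR4 axis, miR-15a/16-1 targets, apoptosis, cell cycle, metabolism, stress, inflammation, neuroblastoma cell identity, matrix and, in 6 lists, markers of host cells; the host endothelial, fibroblast, myeloid, adrenal cortex, blood, and kidney and fat markers were included because the tumours lay in a mouse organ. Lists overlap in some genes. Each was tested against all other genes with camera at its preset correlation of 0.01, adjusted over the 29 lists, and beside it with camera at an estimated correlation and with fry, which asks whether the members move on balance one way. The shift of a list is its mean difference minus that of all other genes, since the median over all genes was -0.02. For p53 targets, the CXCR4 axis, miR-15a/16-1 targets, the unfolded protein, interferon, MYC, respiratory chain, mesenchymal and endothelial lists, the median difference was at or below 0 while camera's direction was up. The genes named were also fixed by rule: 6 genes of prior interest, up to 10 per direction with non-overlapping groups and a difference of at least 0.58 log2 units, about 1.5-fold (all such genes failed the test, so places went by p; 5 genes of small RNA and olfactory receptor type were left out by symbol), and the members with the smallest p, 4 of each called list in the direction of its call and up to 2 of any other list at an unadjusted p under 0.05.

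Both tests were checked on simulated arrays with the means and spread of these genes. For the comparison of BL-8040 with control over 18417 genes, the test recovered 8% of 50 genes changed by 0.3 log2 units, 72% of 50 changed by 0.58, 94% of 50 changed by 1 and 100% of 50 changed by 2, and called 7 unchanged genes. All these genes were changed in the same simulated arrays, with noise independent between genes. For an unchanged list whose members correlated at 0.5, camera with the preset correlation gave p under 0.05 in 56 of 100 simulations and camera with an estimated correlation in 2 of 100. The estimated correlations of the 8 called lists lay between 0.117 and 0.824. Alternatives were a filter on dim genes (median signal, or log2 6), the mean of probe sets, quantile normalization or median centring, a variance trend with robust moderation, array weights, the replicate number as a block, another threshold, and leaving out each array in turn.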

Results

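Gene expression was measured in tumours that grew from SK-N-BE(2) cells, an established human neuroblastoma line with an amplified MYCN gene, after injection into the adrenal gland of NSG mice, a strain that lacks T, B and natural killer cells. Treatment with BL-8040, an inhibitor of the chemokine receptor CXCR4, began 7 days after cell injection at 400 µg under the skin and was given on 14 consecutive days. Tumours of 3 treated and 3 control mice were each read on 1 array of human probe sets. Such an array is made for human transcripts, here those of the tumour cells, and reads mouse RNA only as far as it binds human probes. How much of the signal came from mouse RNA was not measured. Each array gave 1 log2 value per probe set, with a median between 5.35 in control replicate 2 and 5.42 in control replicate 3. After 1 probe set was kept per gene, 18417 named genes were compared. Arrays correlated across genes with r between 0.992 and 0.997, and BL-8040 replicate 3 had the lowest median correlation with the others (0.994). The first principal component held 37.2% of the variance and set BL-8040 replicate 3 (-22.7) apart from the other 5 arrays, which lay between -0.743 and 10.1. With 3 arrays per group, the number of arrays limits the precision: the 95% interval of the difference reached 0.197 log2 units to each side for the median gene.

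The single comparison asked which tumour transcripts changed after CXCR4 inhibition. Among the genes that stood at least 0.58 log2 units (about 1.5-fold) higher after BL-8040 with 3 treated values above all 3 controls was POSTN, which encodes the matrix protein periostin, at 6.45 ± 0.43 against 5.73 ± 0.26 (log2, SD, n = 3 each), a 1.64-fold level. PKDCC, a secreted protein kinase, stood 1.66-fold higher, HS3ST3B1, a heparan sulfate sulfotransferase, 1.53-fold and SLCO2A1, a prostaglandin transporter, 1.59-fold. In all 4 of these genes the highest value was that of BL-8040 replicate 3. Without this array the log2 differences were 0.46 for POSTN, 0.43 for PKDCC, 0.32 for HS3ST3B1 and 0.26 for SLCO2A1, against 0.71, 0.74, 0.62 and 0.67 with all arrays. CRYGS, a crystallin gene, was 1.54-fold higher, and DLEU2, the noncoding host transcript of the miR-15a/16-1 cluster, 1.51-fold. The other 4 of the 10 named higher genes were THUMPD3-AS1 (1.75-fold), LIMD1-AS1 (1.74-fold), FBXL21P (1.58-fold) and ADAD2-AS1 (log2 difference 0.59), antisense or pseudogene transcripts with mean signals at or below percentile 29.6 of all genes. On the other side stood TRIM29, a tripartite motif protein, at 0.557 times the control level, PTGIS, the prostacyclin synthase, at 0.583 times, and RUNDC3A at 0.642 times. ADCYAP1R1, the receptor of the neuropeptide PACAP, stood at 0.646 times, CIART, a repressor in the circadian clock, at 0.649 times, and TARP, a transcript of the T-cell receptor gamma locus that shares sequence with neighbouring segments, at 0.668 times. The lowest value of each of these genes but TARP was that of BL-8040 replicate 3. Without this array the difference of RUNDC3A went from -0.64 to -0.35 and that of CIART from -0.62 to -0.36.

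No gene passed the test. In limma, 0 of 18417 genes had a Benjamini-Hochberg adjusted p under 0.05, and the smallest adjusted p was 0.644. None of the differences named above thus passed once p was adjusted for the number of genes tested. An unadjusted p under 0.05 was reached by 1422 genes, against 921 given by chance alone, of which 487 were higher and 935 lower after BL-8040. With 1 array left out, between 327 and 703 genes were higher and between 578 and 1135 lower at this limma p. The lowest counts, 327 and 578 without control replicate 2, were together below the 921 of chance. The 3 treated values lay wholly above or below the 3 controls in 2575 genes, or 14.0%, where chance gives 10%, and 23 of these genes differed by at least 0.58 log2 units (about 1.5-fold), 15 higher and 8 lower. In simulated arrays with the spread of these data, the same test recovered 72% of genes changed by 0.58 log2 units and 94% of those changed by 1 unit, but 8% of those changed by 0.3. The simulation changed 50 genes of each size at once, with noise independent between genes. With fewer changed genes the adjusted cutoff is stricter, so these shares do not hold for a single changed gene.

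CXCR4, the receptor that BL-8040 blocks, was measured at 3.996 ± 0.29 after BL-8040 and at 4.17 ± 0.22 in controls (log2, SD, n = 3 each), a mean signal at percentile 20.6 of all genes. Its difference of -0.17 had a 95% interval from -0.52 to 0.18 and an adjusted p of 0.769 (limma), and the exact permutation p was 0.4, where 3 against 3 arrays cannot give less than 0.1. With 1 array left out the CXCR4 difference lay between -0.33 (without BL-8040 replicate 2) and -0.07 (without BL-8040 replicate 3). Its ligand CXCL12 differed by 0.08 ± 0.08 (SE) and the second CXCL12 receptor ACKR3 by -0.04 ± 0.07, with adjusted p of 0.781 and 0.886. The 11 measured genes of the CXCR4 axis list, 4 higher and 7 lower, included 0 at an unadjusted p under 0.05. MYCN was among the brightest genes, at 12.23 ± 0.13 after BL-8040 and 12.20 ± 0.03 in controls (SD, n = 3 each), and differed by 0.03, with a 95% interval from -0.15 to 0.22 and an adjusted p of 0.927 (limma).

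**Figure D1:**
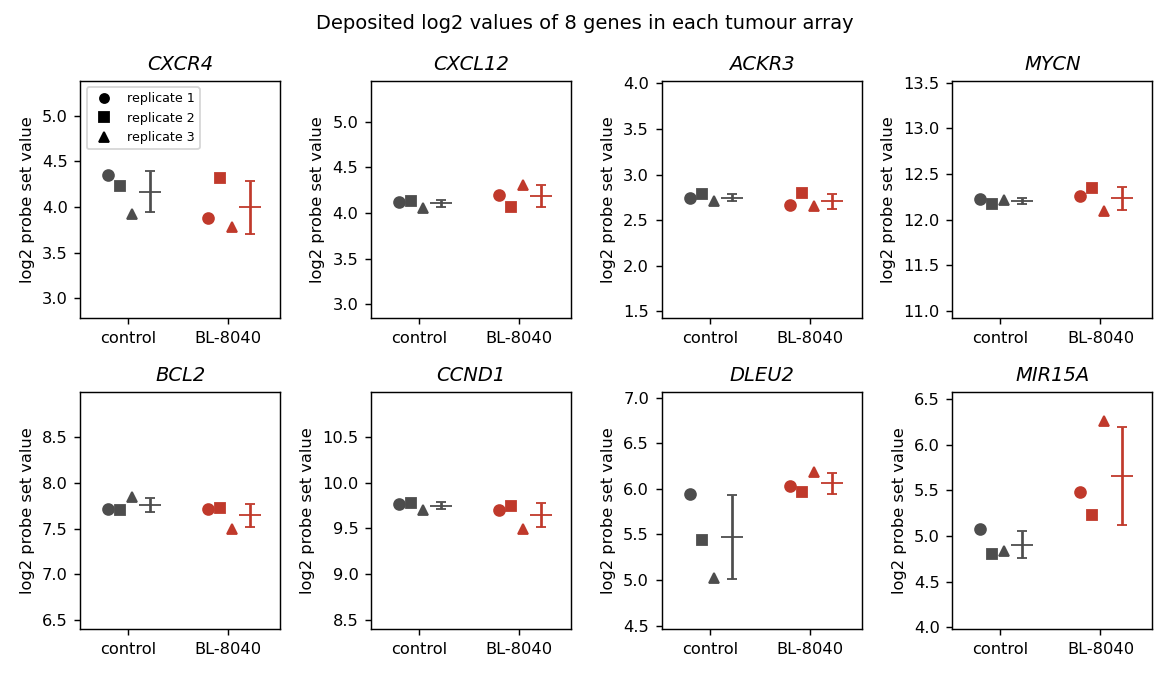
Deposited log2 probe set value (vertical axis, the same span of 2.6 log2 units in every panel) of 8 genes in the 3 control and 3 BL-8040 tumour arrays; each point is 1 array, and the bar beside the points is the group mean with its SD. CXCR4, CXCL12, ACKR3, MYCN, BCL2 and CCND1 overlap between the groups, while the 3 BL-8040 values of DLEU2 and MIR15A lie above all control values.

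Of the transcripts tied to the miR-15a/16-1 cluster, the probe set annotated to MIR15A stood at 5.66 ± 0.54 after BL-8040 and 4.91 ± 0.15 in controls (log2, SD, n = 3 each), a 1.68-fold level with a limma adjusted p of 0.644. Its treated values were 5.48, 5.23 and 6.26. Without BL-8040 replicate 3 the MIR15A difference went from 0.75 to 0.45. MIR15A, MIR16-1 and DLEU1 were singled out after their values were seen. The DLEU2 values were 6.03, 5.96 and 6.18 in the treated arrays and 5.94, 5.44 and 5.02 in the controls. Without control replicate 3 the DLEU2 difference went from 0.59 to 0.37. DLEU2 contains MIR15A and MIR16-1, so their probe sets can read the same precursor, and none of them is known here to read a mature microRNA. MIR16-1 lay at 2.69 ± 0.28 and 2.54 ± 0.14, near the dimmest values of the array, and the neighbouring DLEU1 differed by 0.10 ± 0.08 (SE). Among 27 measured targets of miR-15a/16-1, 13 were higher and 14 lower, and the list did not differ from other genes (camera adjusted p = 0.659). BCL2, an inhibitor of apoptosis, differed by -0.11 and CCND1, the cyclin D1 gene, by -0.10, with 95% intervals from -0.30 to 0.09 and from -0.29 to 0.09 and adjusted p of 0.742 and 0.750. Without BL-8040 replicate 3 the differences were -0.04 for BCL2 and -0.02 for CCND1. The targets with the smallest p stood higher: MCL1, another inhibitor of apoptosis, 1.21-fold and CDC25A, a phosphatase of the G1/S transition, 1.18-fold. The largest difference in the list pointed the other way: VEGFA, which the hypoxia list also holds, differed by -0.64 ± 0.28 (SE). The anti-apoptotic list (8 genes, MCL1 among them) and the pro-apoptotic list (22 genes) gave camera adjusted p of 0.582 and 0.780, and in neither did a gene pass over all genes or adjusted over the list alone.

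All 28 measured hypoxia genes were lower after BL-8040, with a median difference of -0.29, and the list passed the test against other genes (camera adjusted p = 2.71e-06, but adjusted p = 0.871 with an estimated correlation of its members). NDRG1, a stress gene induced by low oxygen, stood at 0.480 times the control level, SLC2A1, the glucose transporter GLUT1, at 0.697 times, ANKRD37 at 0.784 times and PFKFB4, a regulator of glycolysis, at 0.830 times, with limma adjusted p of 0.644 each. NDRG1 was 8.03, 8.73 and 6.84 in BL-8040 replicates 1, 2 and 3 and 8.69, 9.31 and 8.78 in the controls. Without BL-8040 replicate 3 the difference went from -1.06 to -0.54 for NDRG1, from -0.52 to -0.26 for SLC2A1 and from -0.35 to -0.20 for ANKRD37. The list median, relative to each gene's mean over the 6 arrays, was -0.10, 0.13 and -0.43 in the treated arrays and 0.01, 0.31 and 0.11 in the controls, so that BL-8040 replicate 2 lay above 2 of the 3 controls. Without BL-8040 replicate 3 the shift against other genes went from -0.30 to -0.12 (camera adjusted p = 0.0250, but unadjusted p = 0.513 with an estimated correlation), and without BL-8040 replicate 2 to -0.44 (camera adjusted p = 5.91e-14). Of the 16 glycolysis genes, 15 were lower (camera adjusted p = 0.00323, adjusted p = 0.871 with an estimated correlation), led by ENO2 at 0.778 times, GPI at 0.829 times, PFKL at 0.833 times and ALDOC at 0.856 times the control level. The glycolysis call was lost without BL-8040 replicate 3 (camera adjusted p = 0.252; GPI -0.17, PFKL -0.17 and ALDOC -0.15) and without control replicate 2 (0.103; PFKL -0.15 and ALDOC -0.09). Counted per array, the mean of the hypoxia list against other genes was -0.15 ± 0.32 after BL-8040 and 0.15 ± 0.18 in controls (SD, n = 3 each), and the exact permutation p was 0.3 for both lists.

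Genes of the G1/S transition and DNA replication were higher in 27 of 33 cases, with a median difference of 0.11 (camera adjusted p = 6.14e-07, adjusted p = 0.871 with an estimated correlation). RRM2, a subunit of ribonucleotide reductase, was 1.17-fold higher at 8.16 ± 0.05 against 7.93 ± 0.05 (SD, n = 3 each), CLSPN, which encodes the checkpoint adaptor claspin, 1.24-fold, the flap endonuclease gene FEN1 1.16-fold and the DNA polymerase subunit gene POLE2 1.17-fold, with limma adjusted p of 0.644 each. Their differences were below the 0.58 log2 units at which the simulation, with many genes changed at once, recovered 72% of genes. The preset-correlation call was kept whichever array was left out, and the shift went from 0.12 to 0.08 without control replicate 3 (camera adjusted p = 0.00141). The array values overlapped: the list median was 0.08, 0.05 and -0.01 in the treated arrays and 0.03, -0.05 and -0.16 in the controls. The exact permutation p, on the list means, was 0.2. The G2/M and mitosis list, with 28 of 35 genes higher and a median difference of 0.07, also passed (camera adjusted p = 7.48e-04, adjusted p = 0.871 with an estimated correlation), with CENPE 1.25-fold, NDC80 1.20-fold and CCNB1 and KIF23 1.13-fold higher. Its array values overlapped as well: the list median was 0.00, -0.05 and 0.15 in the treated arrays and 0.16, -0.04 and -0.17 in the controls. The call was lost without BL-8040 replicate 3 (camera adjusted p = 0.350; CENPE 0.17, NDC80 0.13 and KIF23 0.11) and without control replicate 3 (0.764), and the shift went from 0.10 to 0.19 without control replicate 1.

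Of 18 cholesterol synthesis genes, 15 were higher after BL-8040, with a median difference of 0.11 (camera adjusted p = 1.39e-04, adjusted p = 0.871 with an estimated correlation). HMGCS1, the synthase at the head of the pathway, was 7.50 ± 0.02 against 7.20 ± 0.12 (log2, SD, n = 3 each), 1.23-fold higher. MSMO1 was 1.19-fold, IDI1 1.18-fold and SQLE, the squalene epoxidase gene, 1.11-fold higher. This was the only called list whose treated arrays had a list median (0.04, 0.06 and 0.03) above that of all controls (-0.01, -0.04 and -0.12) and whose exact permutation p, on the list means, was 0.1, the smallest that 3 against 3 arrays can give. Chance alone gives that permutation p to 10% of lists, and 29 were tested. The call was kept whichever array was left out, with camera adjusted p up to 0.00850. The IDI1 difference went from 0.23 to 0.15 and SQLE from 0.15 to 0.10 without control replicate 3. The ERK pathway list, made of transcripts that follow the activity of this kinase, had 16 of 23 genes higher (camera adjusted p = 0.00507, adjusted p = 0.871 with an estimated correlation). SPRY4 was 1.21-fold, SPRY2 1.19-fold, DUSP6 1.14-fold and SPRED1 1.13-fold higher, all of them inhibitors that the pathway induces. FOSB, another gene that the pathway induces, differed by -0.19 ± 0.10 (SE), and EGR1 had the largest difference of the list, 0.79 ± 0.70 (SE). FOSB and EGR1 were picked out after their values were seen. Counted per array, the means of the ERK list gave an exact permutation p of 0.4. The highest SPRY2 value, 9.79, and the highest DUSP6 value, 9.004, belonged to BL-8040 replicate 2, and without this array the list no longer passed (camera adjusted p = 0.496; SPRY2 0.13 and DUSP6 0.07), nor without control replicate 1 (0.165).

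The adrenergic identity list, which holds regulators and catecholamine genes of noradrenergic neuroblastoma cells, had 22 of 27 genes lower, with a median difference of -0.17 (camera adjusted p = 2.90e-04, adjusted p = 0.871 with an estimated correlation). HAND2, a transcription factor of sympathetic neurons, stood at 0.863 times the control level, SIX3 at 0.862 times, the noradrenaline transporter gene SLC6A2 at 0.888 times and ELAVL4, a neuronal RNA-binding protein, at 0.820 times. The lowest list median, -0.21, was again that of BL-8040 replicate 3, and without it the shift went from -0.18 to -0.08 (camera adjusted p = 0.0642) and the difference of ELAVL4 from -0.29 to -0.14. That of SIX3 went from -0.21 to -0.14 without control replicate 3. Of 58 cytosolic ribosomal protein genes, whose probe sets can also read processed pseudogenes, 51 were lower with a median difference of -0.08 (camera adjusted p = 0.00199, adjusted p = 0.871 with an estimated correlation). RPL13 stood at 0.848 times, RPS29 at 0.890 times, RPL5 at 0.905 times and RPS21 at 0.908 times the control level. The ribosomal list median was -0.14 in BL-8040 replicate 3 and between 0.00 and 0.07 in the other 5 arrays, and the call was lost without that array (camera adjusted p = 0.322), where RPL13 went from -0.24 to -0.12. In all, 4 lists were called higher and 4 lower with the preset correlation, and 0 of 29 with an estimated correlation or with fry, whose smallest adjusted p was 0.683. Without BL-8040 replicate 3, 3 lists were called higher and 1 lower. None of the members of the 8 lists passed over all genes or adjusted over the list alone.

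**Figure D2:**
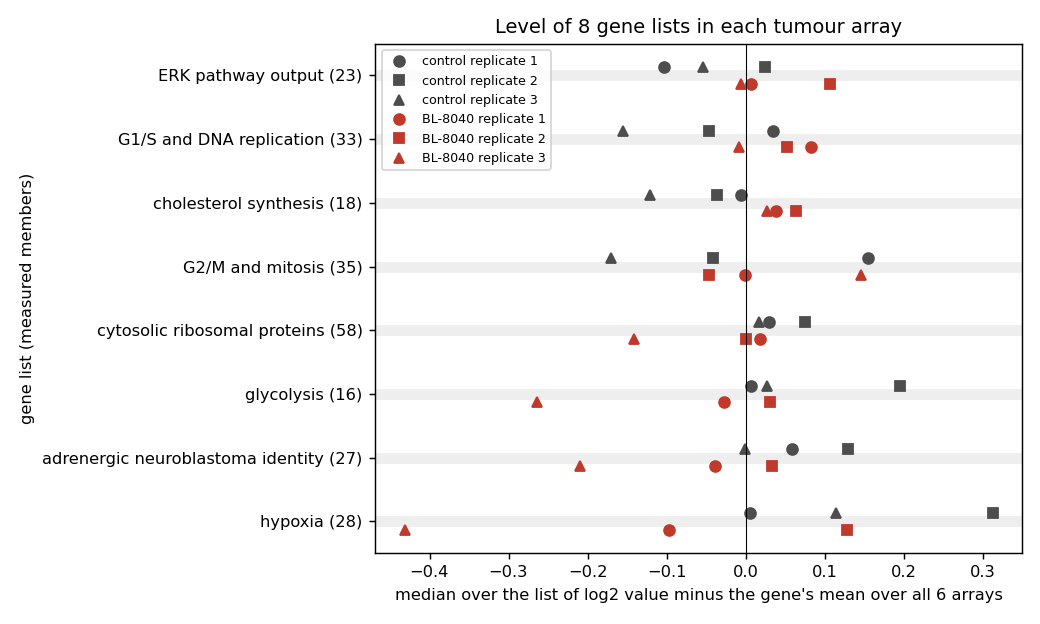
Level of the 8 gene lists called by camera with the preset correlation (vertical axis, with the number of measured members) in each array; the horizontal axis is the median over the list of the log2 value minus the gene's mean over all 6 arrays, and each point is 1 array. BL-8040 replicate 3 is the lowest array for the hypoxia list (-0.43) and the ribosomal list (-0.14), and for cholesterol synthesis the 3 BL-8040 arrays lie above the 3 controls.

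The other lists of tumour cell programmes were not called. Among neuronal differentiation and synapse genes, 24 of 31 were lower (camera adjusted p = 0.239), ENO2 and NGFR (0.772 times the control level) with the smallest p. The mesenchymal list was split into 12 higher and 19 lower genes (adjusted p = 0.780), with FN1, the fibronectin gene, 1.19-fold higher and NOTCH1 at 0.814 times (its difference went from -0.30 to -0.18 without BL-8040 replicate 3). In the matrix and adhesion list (adjusted p = 0.644, 14 higher and 22 lower) POSTN was higher and the integrin gene ITGB3 stood at 0.816 times. Of the NF-kB and inflammation genes, 16 of 22 were lower (adjusted p = 0.289), but the shift of the NF-kB and inflammation list turned from -0.07 to 0.03 when only genes at or above the median signal were kept. TNFAIP2 stood at 0.822 times, whereas NFKBIA, the inhibitor of NF-kB, was 1.16-fold higher at 9.69 ± 0.01 against 9.48 ± 0.07 (SD, n = 3 each). In the angiogenic factor list (adjusted p = 0.741, 9 higher and 14 lower) EFNA1 stood at 0.842 times and VEGFC at 1.17-fold of the control level. The largest falls in log2 value were those of ADM (-0.80), VEGFA (-0.64) and ANGPTL4 (-0.60), all of them also hypoxia list members. THBS1 rose most (0.51). The interferon list (adjusted p = 0.659) held B2M at 1.12-fold and MX2, a dim gene, at 0.865 times. Among stress genes, the chaperone gene HSPH1 stood at 0.820 times (heat shock and oxidative stress list, adjusted p = 0.659), PHGDH, the first enzyme of serine synthesis, at 0.892 times (unfolded protein and ATF4 list, 0.582) and PLK2 at 1.22-fold (p53 target list, 0.289). Of the respiratory chain genes, NDUFC1 stood at 1.14-fold and NDUFB3 at 0.829 times, with 18 of 42 genes higher (adjusted p = 0.741), and of the MYC and MYCN targets 12 of 29 were higher (adjusted p = 0.780). None of the genes in these lists passed over all genes or adjusted over the list alone.

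Lists of host cell markers, read through human probes, were not called either. The endothelial and pericyte list had 14 genes higher and 15 lower (camera adjusted p = 0.954). KCNJ8, a potassium channel of pericytes, stood at 0.693 times the control level, at 7.62 ± 0.20 against 8.15 ± 0.12 (SD, n = 3 each), and EMCN, the endomucin gene, at 1.27-fold. KCNJ8 had a limma adjusted p of 0.644 over all genes and 0.0279 adjusted over the list alone. The latter adjustment was made within each of the 29 lists and not across them, so chance alone can let single genes pass. CFD, the adipsin gene, passed in the same limited sense at 0.750 times the control level in the kidney and adipocyte list (0.0293 adjusted over the list alone, list adjusted p = 0.598), where CIDEA stood at 0.853 times. The mean signals of KCNJ8, EMCN and CFD lay at percentiles 81.3, 96.3 and 62.0 of all genes. On a human array such signals can come from the tumour cells, and their source was not tested. EPB42, an erythrocyte membrane gene, stood at 0.822 times with 0.0393 adjusted over the list alone (erythroid and platelet list, list adjusted p = 0.659). The myeloid list (adjusted p = 0.582) held CSF3R at 0.780 times and LYZ at 1.25-fold, and the adrenal cortex list (0.247) HSD3B1 at 0.877 times, at a mean signal at percentile 4.34. The fibroblast list had 11 genes higher and 11 lower (adjusted p = 0.570) and 0 genes at an unadjusted p under 0.05. On all 6 host lists, the median difference over members lay between -0.08 and 0.03.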

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

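The count of 0 genes called higher and 0 lower held under both filters on dim genes, the mean of probe sets, quantile normalization, median centring, trend with robust moderation, array weights and each array left out. It became 14 higher and 12 lower at an unadjusted p under 0.05 with a difference of at least 0.58 log2 units, and 487 and 935 at an unadjusted p under 0.05 alone, a setting added after seeing the data; the looser criteria are the cause. The 4 lists called higher and 4 called lower became 0 and 0 with an estimated correlation and 0 and 0 with fry, and both allow for the correlation between members. fry also tests the members against no change and not against other genes, so the part of each was not tested. Leaving out 1 array gave 3 to 4 lists called higher and 1 to 4 called lower, the 1 without BL-8040 replicate 3. Array weights called 3 and 3, without the G2/M and mitosis list (adjusted p = 0.0561) and the cytosolic ribosomal proteins list (0.0619). All 8 calls were kept under the filters, the mean of probe sets and both normalizations.

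The replicate numbers are not stated to pair the samples, and the values showed no pairing. Deviations of same-numbered arrays correlated at -0.04, 0.02 and 0.08, and 2 of 6 arrays correlated best with their own number. With 3 arrays per group these values cannot exclude a pairing. With the replicate block, 0 genes were called, 8 of 8 list calls were kept, and the neuronal differentiation and synapse list was added (adjusted p = 0.0381), giving 4 lists higher and 5 lower.

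Sign changes concerned results that were not called, and their cause was not tested. With the filter at the median signal, the shift was -0.016 for miR-15a/16-1 targets, -0.0015 for MYC targets, -0.012 for interferon and 0.028 for NF-kB genes (-0.067 without the filter); with the filter at log2 6 it was -0.016, -0.0012 and -0.012 for the first 3. The mean of probe sets gave -0.0036 for miR-15a/16-1 targets, and array weights gave -0.0013 for mesenchymal and -0.016 for endothelial genes. Leaving out 1 array gave ranges of -0.021 to 0.016 (miR-15a/16-1 targets), -0.012 to 0.032 (MYC targets), -0.000392 to 0.014 (interferon response list), -0.020 to 0.049 (mesenchymal), -0.036 to 0.036 (endothelial), -0.0058 to 0.043 (respiratory chain), -0.030 to 0.030 (matrix), -0.036 to 0.0042 (pro-apoptotic), -0.054 to 0.00616 (myeloid markers list), -0.051 to 0.000805 (erythroid and platelet markers list) and, for the MYCN difference, -0.0244 to 0.0990. CXCR4 stayed lower and uncalled in every fit that tested it; both filters removed it.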

Other observations

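Apart from the shifts of the hypoxia list and the microRNA target list, which were fixed beforehand, the tests in this part were chosen after the data were seen. The clock gene test was written before its result, once CIART had been named.

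Several gene families outside the fixed lists also leaned one way. Of 73 genes with a histone symbol, which include pseudogenes and an antisense RNA and whose near-identical copies can share probes, 49 were higher after BL-8040, among them H2BC7 by 0.32 ± 0.11 and H2BC6 by 0.24 ± 0.08 (SE), with list medians of 0.13, 0.02 and -0.06 in the treated arrays and 0.00, -0.02 and -0.04 in the controls. Of 45 genes for proteasome subunits and their assembly and regulator proteins, 34 were higher, with PSMA3 higher by 0.24 ± 0.10 and PSMA7 by 0.16 ± 0.07. Both families passed camera with the preset correlation (adjusted p over the 8 families and lists examined afterwards of 2.27e-04 and 0.00180) and neither did with an estimated correlation (unadjusted p = 0.208 and 0.204). Of 192 small nucleolar RNA genes, 118 were higher (adjusted p = 2.27e-04, and unadjusted p = 0.247 with an estimated correlation), and single members went far in both directions, SNORA41 at 1.53-fold and SNORA60 at 0.606 times the control level. Each of these calls with the preset correlation was lost without 1 array: the histone shift went from 0.074 to 0.037 without BL-8040 replicate 1 (adjusted p = 0.128), the proteasome shift from 0.063 to 0.039 without control replicate 3 (0.0692) and the small nucleolar RNA shift from 0.076 to 0.020 without control replicate 2 (0.299). Glucocorticoid targets were not called as a list beside SGK1, a serum- and glucocorticoid-induced kinase gene that stood 1.33-fold higher. Of these targets, 8 of 11 were lower, and the list shifted by 0.015 against other genes (limma's camera, adjusted p = 0.827 over the 8), a sign that turned without BL-8040 replicate 1 (-0.0070) or control replicate 1 (-0.022). The genes with the smallest unadjusted p included TLR6, a Toll-like receptor gene (1.44-fold higher), and PWAR6, a dim noncoding transcript (1.47-fold higher).

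BL-8040 replicate 3 held the highest values of IGFBP7 (8.74, against 6.92 to 7.19 in the other arrays) and KLHL6 (7.90, against 6.39 to 6.77), besides the genes described above. Without this array the differences of IGFBP7 and KLHL6 went from 0.66 to 0.13 and from 0.62 to 0.23. Among the 10 ways to split the 6 arrays into 3 and 3, the real split gave 0 called genes and the highest of the other splits 0; against a count of 0 all 10 splits give as many, which says nothing on chance. The real split gave 8 called lists and the highest other split 10, and 5 of the 10 splits gave 8 or more. With 10 splits no share under 0.05 can be reached. At an unadjusted p under 0.05 the real split gave 1422 genes and the highest other split 1232. The unnamed probe sets held 0 of 12083 called in limma (956 at an unadjusted p under 0.05), and those with several symbols 0 of 1754 (107).

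Among the 8 called lists, the hypoxia list had the widest spread between treated tumours. Other genes of like signal did not fall as far, which argues against a scaling of all genes at that signal as the whole of the difference. The median difference of the list over all arrays was -0.29. It lay below that of all 10000 random lists matched on signal, of which the lowest was -0.10, giving percentile 0.01, the smallest they can give. This percentile is no measure of chance. The list had already been called lower than other genes, and its members correlated at 0.824, while random members were drawn independently. Whether 1 tumour accounts for the shift stays open, since without BL-8040 replicate 3 it was -0.125, with a 95% interval from -0.640 to 0.391 from the spread between arrays, and 25 of 28 genes stayed lower. With all arrays that interval ran from -0.884 to 0.293. A lower oxygen response after CXCR4 inhibition, and a difference in tumour size or perfusion, may each be involved; neither was tested.

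Dim genes leaned lower after BL-8040: below the median signal the median difference was -0.038 and 62.9% of genes were lower, with 664 lower and 225 higher at an unadjusted p under 0.05, against 271 and 262 in the brighter genes. A candidate explanation is the background level of the arrays. Olfactory receptor genes, taken here as genes with little or no tumour transcript, had a median difference of -0.0383 and 60.9% of 361 lower, the same as other dim genes (-0.0383), as that explanation needs. Without control replicate 3, the array with the highest dim values, the olfactory receptor median was -0.0097 and that of all dim genes -0.0237. The olfactory receptor lean thus rested largely on that array. In the same fit, 664 of all genes were still lower and 355 higher at an unadjusted p under 0.05 (limma). Whether background accounts for part of the excess of lower genes stays open. TARP, ADCYAP1R1, CIART, EPB42 and CSF3R, named above as lower, have mean signals within the dim range. So do others named above, among them CXCR4 and PFKFB4, which were lower, and THUMPD3-AS1 and LIMD1-AS1, which were higher. The differences of TARP (-0.58) and EPB42 (-0.28) were much larger in size than the dim median of -0.038. TARP was named for the size of its difference and EPB42 for its small p, so this contrast says nothing on background.

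The MIR15A probe set and its host DLEU2 stood higher together. The microRNA genes as a family were also called higher (104 of 189, shift 0.069, camera adjusted p = 0.00582, unadjusted p = 0.283 with an estimated correlation), but not without BL-8040 replicate 3 (shift 0.036, adjusted p = 0.231) or control replicate 2 (0.028, 0.471), so a small common rise of small RNA probe sets stays open. The MIR15A difference was 0.750 with all arrays and 0.446 without BL-8040 replicate 3. The other 188 microRNA probe sets had a median difference of 0.0155 with all arrays. Their SD was 0.181, and 0 of them reached 0.750. MIR15A was singled out after its value was seen, so neither its rank among them nor its distance from their median is evidence. This comparison therefore cannot tell whether MIR15A differed by more than a common rise. More mature miR-15a acting on its targets stays open as a hypothesis, since the fixed target list shifted by 0.00262 with a 95% interval from -0.072 to 0.077, which neither shows a fall nor excludes one of 0.05. Probes that DLEU2 and MIR15A may share were not examined.

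CIART, at 0.649 times the control level, raised the hypothesis that tumours differed in clock phase at harvest. Of 9 other clock output genes, 7 were lower, NR1D1 furthest at -0.26 ± 0.09 (SE), and the antiphase genes shifted by 0.028, with 3 of 5 lower, and by -0.035 without control replicate 3. The shift of the clock output genes was -0.0641 (limma's camera, adjusted p = 0.147 over the 8 families and lists, and unadjusted p = 0.395 with an estimated correlation), which leaves the hypothesis open; without BL-8040 replicate 3 this shift was -0.043, without control replicate 3 it was -0.041, and without BL-8040 replicate 1 it was -0.097 (adjusted p = 0.0387 with the preset correlation).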
